A study of Mus musculus with 35 samples.

How the data were processed

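RNA was measured by sequencing in 35 libraries of mouse embryonic fibroblasts (embryonic day 13.5, passage 2) after 48 hours of infection with retroviral factors and up to 7 days in iCD3 medium. The submitters' notes name bcl2fastq, Bowtie2 and RSEM with the mm10 genome build, and give no versions and no annotation release. The authors deposited 1 RSEM gene table per library, whose expected count column holds estimated read counts, not normalized and not whole in all cases, per the file headers and the values. Per the file headers the same tables give TPM, which sum to the same total in each library, and FPKM, which was not used in any test. They also give transcript lengths and effective lengths. Each table holds 54752 genes, of which 54723 were matched to a symbol by Ensembl identifier, and 102 identifiers that share a symbol with a gene of higher count kept the identifier.

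Arms and days were taken from the sample names. A treatment label that gives all 4 factors to every sample contradicts those names, and the names were used because the level of each factor followed them. The series text describes another number of samples, and it names a pair of library kits and sequencing runs without saying which library had which, so no batch term was fitted. The retroviral and endogenous transcripts of a factor are counted together. Reads shared between paralogs were divided by RSEM, so counts of Dcpp, Zscan4, Serpinb9 and alpha globin family members are uncertain.

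Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, genes at 1 CPM or more in at least 3 libraries of the fit, the quasi-likelihood fit with a trended dispersion, and the quasi-likelihood F test, which is two-sided. The 4 leave-out contrasts came from a fit of the 32 leave-out libraries with day as a factor and arm, each arm against the mean of the other 3. JEGS was compared with the mean of the 4 leave-out arms, and with each of them, in a fit of the 15 libraries of days 2, 4 and 6 with day as a factor and arm. Day trends came from a fit of the 32 leave-out libraries with a linear day slope per arm, as the mean slope and as each arm's slope minus the mean of the other 3, and for JEGS from the 15 libraries in the same way. That makes 15 contrasts. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. CPM values are TMM scaled. Where an arm has no count of a gene, the fold is given as a bound, from a floor of 3 counts over the libraries of that group. Intervals and floors cover counting error only.

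Depth was 1266379 to 3608456 counts per library. On simulated counts of the same depths with 100 changed genes per size, the leave-out fit recovered 84 genes of a true log2 change of 1 and 100 of 2, and the JEGS fit recovered 34 and 92. The common slope was recovered in 100 of 100 genes at 0.25 per day.

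Gene lists were written by hand from general knowledge before the data were examined, as were the samples' groups, the tests, the alternatives and the rule for naming genes. The 30 lists cover the pluripotency network, fibroblast and mesenchymal identity, epithelial genes, AP-1 subunits, AP-1 responsive genes, SRF and YAP targets, p53 targets and senescence, cell cycle, interferon response, glycolysis, oxidative phosphorylation, cholesterol synthesis, unfolded protein and amino acid stress, the NuRD complex, BMP targets, Wnt targets, primitive endoderm, trophoblast, the 2-cell stage, germ line, macrophage, endothelial, neural, muscle, keratinocyte, cartilage and bone, adipocyte, red blood cell, sex-linked genes and mitochondrial transcripts. Each was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 444 tests, and again with an estimated correlation. Counts adjusted over the list alone take the Benjamini-Hochberg step over the list's measured genes. Medians are given only for lists without genes at 0 in an arm.

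Genes are named by a rule with 3 parts. The 4 factors are given in every library. From each list described, up to 4 members with the largest change past the threshold are named. From each contrast, the top 5 genes in each direction (leave-out contrasts, JEGS against the mean, common trend) or the top 2 (other contrasts) are named, among genes past the threshold with a mean of at least 5 CPM and the same sign on every day or in every arm, without predicted genes and the factors. A few genes that this rule names are not reported here.

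Alternatives tried were the DESeq2 1.42.0 Wald test, DESeq2 size factors, no filter, limma-trend on log2(TPM + 1) with genes at 1 TPM or more in 3 libraries, no day term, days 3 to 7, arm slopes added to the day factor, all 35 libraries in the fit, log2(day + 1), and leaving out each library and each day. Thinning of every library to 1200000 counts was added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots. To see whether other groupings give as many genes, arm labels were rearranged within days, or days within arms, and the fit repeated. For slope differences, days were also rearranged in the arm-specific slopes alone, with the common slope on the true days kept in the fit.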

Results

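Mouse embryonic fibroblasts that carry a green fluorescent reporter of Oct4 (Pou5f1) were infected with retroviruses for Jdp2, Glis1, Esrrb and Sall4, a set called JEGS here, or for 3 of these 4 factors. After infection they were kept in iCD3 medium, an induction medium for reprogramming to pluripotency, for up to 7 days. RNA sequencing was done on 35 libraries. The 4 leave-out arms, each lacking 1 factor, have 8 libraries each, 1 per day from day 0 to day 7, and the JEGS arm has 3 libraries, from days 2, 4 and 6. Total expected counts ran from 1266379 to 3608456 per library, with a median of 1973102, so 1 count corresponded to 0.277 to 0.79 CPM, the count scaled to library size. No arm has a replicate of any day, and the labels do not say whether libraries of an arm are separate cultures. Each arm is therefore read as 1 culture series, and p-values measure the spread between these libraries, not between cultures. JEGS libraries are marked as a second repeat in their names and leave-out libraries are not. A batch difference between JEGS and the leave-out arms therefore cannot be told apart from the extra factor. Kits and sequencing runs are not assigned to libraries, so a batch difference among the leave-out arms cannot be told apart from the missing factor either.

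The 4 delivered factors followed the sample names. Esrrb stood at 7.06 to 57.9 CPM in the 8 libraries without it, against 962 to 2594 CPM in the 3 JEGS libraries and 4015 to 8358 CPM in the arm without Glis1. Glis1 reached at most 4.44 CPM in the arm without it and 84.5 to 534 CPM in every other library. Jdp2 stood at 10.4 to 45.4 CPM in the arm without it and 258 to 3535 CPM elsewhere, and Sall4 at 0.58 to 11.2 CPM against 625 to 5572 CPM. Delivered factors fell late in the series in more than 1 arm. Without Jdp2, Esrrb went from 2645 CPM on day 2 to 539 CPM on day 7, and Sall4 from 2751 CPM on day 3 to 625 CPM on day 7. In the arm without Esrrb, Jdp2 went from 1615 CPM on day 1 to 428 CPM on day 6 and Sall4 from 5402 to 1861 CPM. In JEGS, Esrrb went from 2594 CPM on day 2 to 962 CPM on day 6. Counts do not separate transcripts of the retrovirus from those of the endogenous gene.

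**Figure D1:**
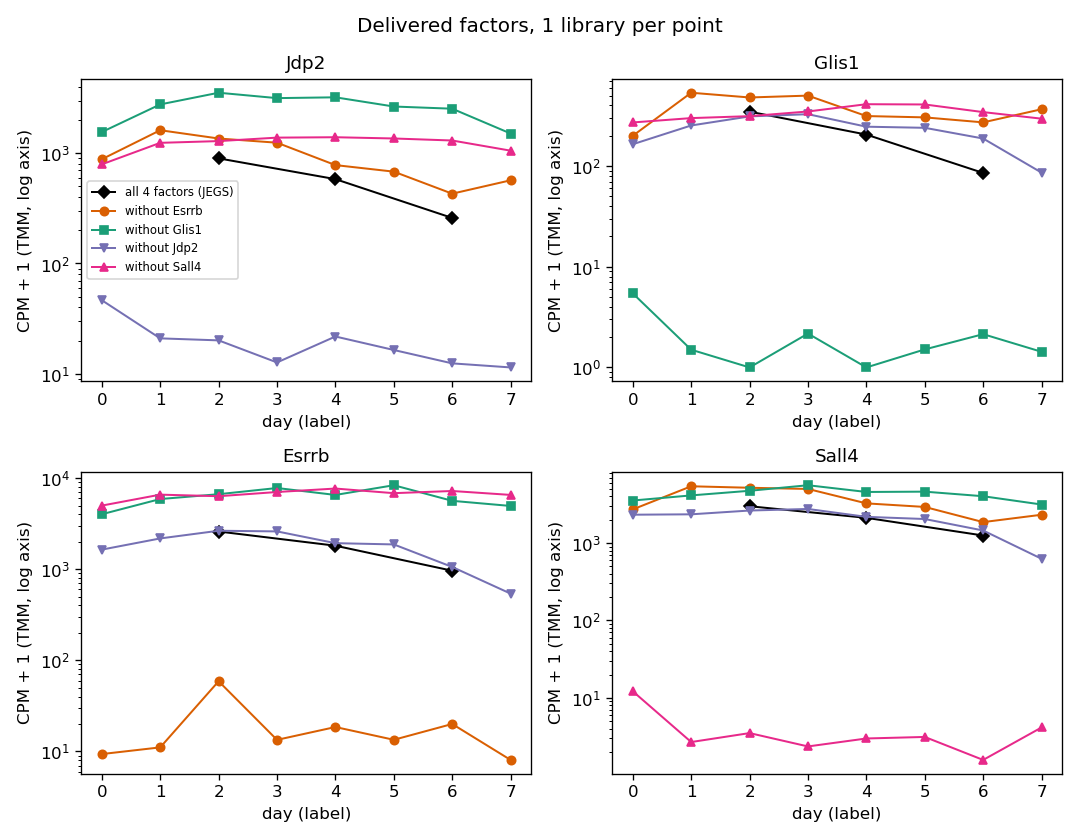
Level of each delivered factor by day on a log axis (CPM + 1, TMM scaling), with 1 point per library and 1 line per arm. In the arm that lacks it, each factor lies below its level in all other libraries, for example at most 4.44 CPM for Glis1.

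The leave-out comparisons ask what differs during the induction in the arm that lacks each factor. Each sets the 8 libraries of an arm against the 24 libraries of the other 3 leave-out arms, day by day, as log2 fold changes ± standard error (SE) from edgeR. All these reference arms lack a factor too, and the 4 contrasts sum to 0, so they are not independent of each other. They do not show the effect of losing a factor from the complete set, and the direction can differ against JEGS. For example, pluripotency genes were higher without Jdp2 in 16 of 25, yet JEGS was higher than that arm in 9 of 27. The factors still delivered also differed in level between arms. Before TMM scaling and over all days, Esrrb averaged 6135 and 6145 CPM without Glis1 and Sall4, but 1803 CPM without Jdp2. Jdp2 averaged 2577 CPM without Glis1, against 1005 and 1133 CPM without Esrrb and Sall4. Libraries of the arms differed as well. Fragment length ran from 200.6 to 204.7 bases without Esrrb. It ran from 205.7 to 209.5 without Jdp2 and 206.8 to 211.7 without Sall4, both apart from that range. Without Glis1 it ran from 201.2 to 212.3 and overlapped all of these. Total counts were 1377656 to 1651712 without Esrrb and at least 1672386 in the other leave-out arms. The absence of a factor, the levels of the other factors and a batch cannot be told apart in the leave-out contrasts.

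Without Esrrb, cell cycle genes and Wnt targets were higher and respiratory genes were lower. Of 28 cell cycle genes, 26 were higher, and 26 adjusted over the list alone, with a median of 1.24 (camera adjusted p = 2.9e-13, and adjusted p = 0.35 with an estimated correlation). Among them Top2a was higher by 1.85 ± 0.23, Aurkb by 1.70 ± 0.22 and Mcm3 by 1.69 ± 0.18. Cartilage and bone genes divided, with 4 higher and 4 lower of 12, the same counts adjusted over the list alone, and the list did not pass as a set (camera adjusted p = 0.29). Its higher members included the bone regulator Sp7 at 5.90 ± 0.29 and the cartilage genes Col9a1 at 4.59 ± 0.33 and Matn1 at 4.48 ± 0.50. Endothelial genes were higher in 6 of 12 and lower in 3, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.042, and adjusted p = 0.51 with an estimated correlation). Of these Sox18 was higher by 4.13 ± 0.30 and Cdh5 by 3.06 ± 0.28. Wnt targets were higher in 14 of 16, also 14 adjusted over the list alone (camera adjusted p = 5.8e-06, and adjusted p = 0.31 with an estimated correlation). These included the secreted inhibitors Wif1 at 3.85 ± 0.27 and Notum at 2.33 ± 0.29 and Lef1 at 2.51 ± 0.25. Of 13 BMP targets, 7 were higher and 2 lower, or 8 and 2 adjusted over the list alone, with Msx1 at 3.80 ± 0.18 (camera adjusted p = 0.0051, and adjusted p = 0.35 with an estimated correlation). In the other direction, 24 of 25 oxidative phosphorylation genes were lower, also 24 adjusted over the list alone, with a median of -0.55 (camera adjusted p = 6.7e-10, and adjusted p = 0.35 with an estimated correlation), for example Cox5a at -1.53 ± 0.14. AP-1 responsive genes were lower in 10 of 18 and higher in 1, or 13 and 1 adjusted over the list alone (camera adjusted p = 0.00029, and adjusted p = 0.35 with an estimated correlation). Among them were Spp1 at -3.73 ± 0.29 and Plau at -2.37 ± 0.33. SRF and YAP targets were lower in 10 of 17, also 10 adjusted over the list alone, with Ccn2 at -2.02 ± 0.22 (camera adjusted p = 0.0017, and adjusted p = 0.36 with an estimated correlation). Without a day term Ccn2 stood at -1.24 and failed to pass. p53 targets and senescence genes were lower in 12 of 19 and higher in 2, or 13 and 2 adjusted over the list alone, with the senescence gene Cdkn2b at -2.04 ± 0.23 (camera adjusted p = 0.0011, and adjusted p = 0.35 with an estimated correlation).

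The largest single differences without Esrrb included genes outside these groups, in the same direction on all 8 days. The adhesion gene Lrrc4b was higher by 6.13 ± 0.28 (adjusted p = 2.4e-15) and the collagen gene Col8a2 by 6.90 ± 0.48. The secreted salivary proteins Dcpp2 and Dcpp3 were higher by 7.23 ± 0.45 and 6.86 ± 0.42, and Dcpp1 averaged 243 CPM against 5.34 CPM, but reads shared among these paralogs make each of the 3 values uncertain. On the lower side stood Paqr5 at -6.15 ± 0.79, Ano5 at -6.04 ± 0.43, Psca at -5.90 ± 0.53 and Hp at -5.72 ± 0.53. Without day 2, Hp stood at -9.32. Serpinb9g, a member of a family with close paralogs, had no count in this arm and was at least 29.4-fold lower. Pluripotency genes divided, with 6 higher and 4 lower of 25, or 5 and 4 adjusted over the list alone (camera adjusted p = 0.51). Lin28a was higher by 4.61 ± 0.57 and Pou5f1 by 2.81 ± 0.56, while the orphan receptor Nr0b1 stood at -5.28 ± 0.60. The Pou5f1 difference did not hold against each reference arm. Before TMM scaling it averaged 13.46 CPM here, 20.75 CPM without Jdp2, and 3.49 and 0.27 CPM without Glis1 and Sall4. From day 5 on Pou5f1 was lower here than without Jdp2, at 6.95 against 81.29 CPM on day 7. In all, 7767 of 18135 genes passed, 3798 higher and 3969 lower, a balance that turned under other scalings, for example to 4098 and 3655 with DESeq2 size factors.

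Without Glis1, interferon-stimulated genes were higher and genes of proliferation and contractility were lower. Interferon genes were higher in 22 of 23, also 22 adjusted over the list alone, with a median of 3.27 (camera adjusted p = 5.2e-11, and adjusted p = 0.35 with an estimated correlation). Ifi44 was higher by 5.28 ± 0.35, Ifit1 by 4.49 ± 0.48, Usp18 by 4.40 ± 0.47 and Mx2 by 4.14 ± 0.49. p53 targets and senescence genes were higher in 12 of 19 and lower in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.00024, and adjusted p = 0.35 with an estimated correlation). Members included Gdf15 at 3.03 ± 0.25, Fas at 1.56 ± 0.25 and Cdkn1a at 1.55 ± 0.18. Cell cycle genes were lower in 13 of 28 and higher in 1, or 17 and 1 adjusted over the list alone, with a median of -0.57 (camera adjusted p = 0.00032, and adjusted p = 0.64 with an estimated correlation). Top2a stood at -1.12 ± 0.27. SRF and YAP targets were lower in 11 of 17 and higher in 3, with the same counts adjusted over the list alone and Ankrd1 at -2.09 ± 0.38 (camera adjusted p = 0.043, and adjusted p = 0.58 with an estimated correlation). BMP targets were lower in 6 of 13 and higher in 2, or 8 and 2 adjusted over the list alone, with Hey1 at -3.94 ± 0.37 (camera adjusted p = 0.025, and adjusted p = 0.35 with an estimated correlation). Some lists went both ways and did not pass as sets. Endothelial genes were lower in 5 of 12 and higher in 2, the same counts adjusted over the list alone, with Sox18 at -5.89 ± 0.56 (camera adjusted p = 0.085). Wnt targets were higher in 5 of 16 and lower in 3, or 5 and 4 adjusted over the list alone, with Wif1 at -5.82 ± 0.47 (camera adjusted p = 0.83). Pluripotency genes were higher in 2 of 25 and lower in 2, or 2 and 1 adjusted over the list alone, with Sox2 at -3.81 ± 0.29 (camera adjusted p = 0.86).

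The largest rises without Glis1 were the glutathione peroxidase Gpx6 at 7.34 ± 0.30, Ly6d at 7.20 ± 0.29, the peptidase Ace at 7.16 ± 0.26, the mitochondrial carrier Slc25a34 at 7.04 ± 0.23 (adjusted p = 8.6e-19) and the basement membrane collagen Col4a3 at 6.84 ± 0.37. The insulin gene Ins2 was lower at -7.33 ± 0.74. Il9r and Itih3 had no count in this arm and were at least 79.8-fold and 52.3-fold lower, and of the salivary paralogs Dcpp1 was at least 478-fold lower. Of 8 genes of the 2-cell stage, 7 were higher, or 8 adjusted over the list alone, though the list as a set did not pass (camera adjusted p = 0.055). Their summed level was 106 CPM on day 1 and 39.6 CPM on day 2 in this arm, against at most 5.92 CPM in any other library. Members of the Zscan4 family have close paralogs, so the values of its single genes are uncertain. Here 6586 of 18135 genes passed, 3626 higher and 2960 lower, but limma-trend on TPM gave 2393 higher and 3224 lower.

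Without Jdp2, epithelial, primitive endoderm and pluripotency genes were higher together. Primitive endoderm genes were higher in 15 of 18, or 16 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.3e-09, and adjusted p = 0.29 with an estimated correlation). Ttr was higher by 2.69 ± 0.45 and Sox7 by 2.27 ± 0.27, and Sox17 averaged 20.5 CPM against 2.39 CPM. Epithelial genes were higher in 15 of 23 and lower in 1, or 17 and 1 adjusted over the list alone (camera adjusted p = 3.1e-06, and adjusted p = 0.31 with an estimated correlation). These included Krt8 at 3.57 ± 0.38 and Krt19 at 3.25 ± 0.27. Pluripotency genes were higher in 16 of 25, or 17 adjusted over the list alone (camera adjusted p = 2.3e-06, and adjusted p = 0.35 with an estimated correlation). Among them was Tdgf1 at 3.76 ± 0.60. Cell cycle genes were higher in 24 of 28, or 26 adjusted over the list alone, with a median of 0.85 (camera adjusted p = 8.0e-12, and adjusted p = 0.35 with an estimated correlation), and Top2a was higher by 1.24 ± 0.23. Glycolysis genes were higher in 9 of 18 and lower in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.0041, and adjusted p = 0.56 with an estimated correlation). Members included the transporters Slc16a3 at 2.63 ± 0.39, Slc2a3 at 2.49 ± 0.25 and Slc2a1 at 1.71 ± 0.17. Contractile SRF and YAP targets were higher in 10 of 17, or 10 higher and 1 lower adjusted over the list alone, with Ankrd1 at 2.61 ± 0.27 and Tagln at 2.28 ± 0.28 (camera adjusted p = 0.00083, and adjusted p = 0.35 with an estimated correlation). Without a day term these 2 genes stood at 1.61 and 0.48 and failed to pass, and Tdgf1 failed with arm slopes added. AP-1 responsive genes were higher in 9 of 18, or 10 adjusted over the list alone (camera adjusted p = 0.00097, and adjusted p = 0.40 with an estimated correlation). Interferon genes were lower in 18 of 23 and higher in 1, or 19 and 1 adjusted over the list alone, with a median of -1.85 (camera adjusted p = 3.7e-06, and adjusted p = 0.49 with an estimated correlation). This is relative to a reference that includes the raised arm without Glis1. On day 6 their mean log2(CPM + 1) was 2.01 here, 1.98 without Esrrb and 2.76 in JEGS, against 3.50 without Sall4 and 6.58 without Glis1. In JEGS against this arm none of 22 passed by edgeR (camera adjusted p = 0.085, and adjusted p = 0.80 with an estimated correlation).

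Top differences of the arm without Jdp2 were of the same sign on all 8 days. AU015836 was higher by 6.70 ± 0.26, the mitochondrial protein gene Efhd1 by 4.62 ± 0.36, the endothelial cadherin Cdh5 by 4.38 ± 0.26, the cytokine Il11 by 4.37 ± 0.37 and Cilp by 4.14 ± 0.19. Adgrf1 was lower at -4.78 ± 0.58, Cdhr1 at -4.10 ± 0.66, Col4a3 at -4.00 ± 1.19, the potassium channel Kcnt1 at -3.98 ± 0.55 and the fatty acid receptor Ppara at -3.91 ± 0.59. Col4a3 failed to pass in 5 of 49 alternative settings. Endothelial genes as a list were higher in 8 of 12 and lower in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.0016, and adjusted p = 0.35 with an estimated correlation). These included Flt1 at 2.71 ± 0.22. The embryonic globin Hba-x appeared late, at 2.27, 13.0 and 23.2 CPM on days 5 to 7, and 3 of 6 red blood cell genes were higher, or 4 adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.35 with an estimated correlation). In this contrast 4269 genes passed, 2613 higher and 1656 lower, the fewest of the 4.

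Without Sall4, genes of proliferation, pluripotency and epithelium were mostly lower. Genes of respiration were higher, and more fibroblast genes were higher than lower. Cell cycle genes were lower in 27 of 28, also 27 adjusted over the list alone, with a median of -1.58 (camera adjusted p = 1.4e-16, and adjusted p = 0.35 with an estimated correlation). Among them were Kif11 at -2.01 ± 0.27 and Top2a at -1.96 ± 0.29. Pluripotency genes were lower in 12 of 25 and higher in 3, or 14 and 3 adjusted over the list alone (camera adjusted p = 0.037, and adjusted p = 0.57 with an estimated correlation). Lin28a stood at -5.05 ± 0.91 and Pou5f1 at -4.81 ± 0.85, and Utf1 had no count in this arm and was at least 9.74-fold lower. Epithelial genes were lower in 15 of 23 and higher in 3, or 15 and 4 adjusted over the list alone (camera adjusted p = 0.003, and adjusted p = 0.35 with an estimated correlation). Members included Tjp3 at -3.72 ± 0.65 and Epcam at -2.69 ± 0.50. Wnt targets were lower in 12 of 16 and higher in 1, or 13 and 1 adjusted over the list alone (camera adjusted p = 4.4e-05, and adjusted p = 0.34 with an estimated correlation). Of these Rnf43 stood at -3.28 ± 0.42 and T was at least 36.7-fold lower. Fibroblast genes were higher in 14 of 29 and lower in 6, or 16 and 7 adjusted over the list alone (camera adjusted p = 0.049, and adjusted p = 0.35 with an estimated correlation). These included Col3a1 at 2.21 ± 0.16 and Lox at 2.06 ± 0.21, though Lox failed to pass without a day term. AP-1 responsive genes were higher in 11 of 18, or 11 higher and 1 lower adjusted over the list alone, with a median of 1.27 (camera adjusted p = 8.0e-05, and adjusted p = 0.35 with an estimated correlation). Among them were Spp1 at 2.39 ± 0.20 and Mmp3 at 1.89 ± 0.37. Oxidative phosphorylation genes were higher in 24 of 25, or 25 adjusted over the list alone, with a median of 0.62 (camera adjusted p = 8.3e-10, and adjusted p = 0.35 with an estimated correlation), for example Ndufb7 at 0.95 ± 0.13. The YAP target Ccn2 was higher by 3.27 ± 0.17, and glycolysis genes were lower in 10 of 18 and higher in 2, or 11 and 2 adjusted over the list alone, with Slc2a3 at -3.35 ± 0.37 (camera adjusted p = 0.033, and adjusted p = 0.66 with an estimated correlation).

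The largest rises without Sall4 were the angiotensin receptor Agtr2 at 5.58 ± 0.29, Clca3a1 at 5.29 ± 0.29, Ankrd63 at 5.23 ± 0.30 and Serpina3g at 5.15 ± 0.44. Serpinb9g averaged 16.4 CPM against 1.25 CPM, with reads shared among its paralogs. Sox17 had no count in the 8 libraries and was at least 60.2-fold lower. Svopl was lower at -6.71 ± 0.54, the hormone precursor Trh at -5.88 ± 0.86, Col8a2 at -5.11 ± 0.95 and the RNA-binding gene L1td1 at -4.92 ± 0.56. In this contrast 7586 genes passed, 4050 higher and 3536 lower, but limma-trend on TPM gave 2560 higher and 3684 lower.

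The comparison of JEGS with the leave-out arms asks what the complete set adds, on days 2, 4 and 6, with 3 libraries against 12. Pluripotency genes were higher in 23 of 27, also 23 adjusted over the list alone (camera adjusted p = 7.7e-23, and adjusted p = 0.31 with an estimated correlation). Nanog was higher by 5.46 ± 0.52 (adjusted p = 2.3e-05), Pou5f1 by 4.77 ± 0.52 and L1td1 by 4.63 ± 0.32 (adjusted p = 1.4e-06). Pou5f1 went from 16.2 CPM on day 2 to 104 CPM on day 4 and 372 CPM on day 6, and Nanog from 6.95 to 38.7 and 145 CPM. Utf1 averaged 45.9 CPM in JEGS against 1.15 CPM, and the Nodal inhibitor Lefty2 averaged 22.0 CPM against 1.87 CPM. Cell cycle genes were higher in 19 of 28, or 27 adjusted over the list alone, with a median of 1.03 (camera adjusted p = 1.1e-20, and adjusted p = 0.35 with an estimated correlation). Members included Mcm5 at 1.40 ± 0.29, Ccnb1 at 1.39 ± 0.24 and Mcm6 at 1.37 ± 0.18. This rise was not against every arm, as given below. Wnt targets were higher in 7 of 16, or 10 adjusted over the list alone (camera adjusted p = 3.5e-06, and adjusted p = 0.29 with an estimated correlation). These included Cdx1 at 2.17 ± 0.45 and Notum at 1.37 ± 0.20. The rise of Wnt targets was not against every arm either, as given below. Epcam was higher by 2.71 ± 0.43 and the transporter Slc2a3 by 2.45 ± 0.24. Mcm5, Ccnb1, Cdx1, Epcam and Notum each failed to pass in 2 of 21 alternative settings. Without the day 6 library of JEGS, Mcm5 stood at 0.79 and Cdx1 at 1.31. Fibroblast genes were lower in 2 of 29, or 4 adjusted over the list alone (camera adjusted p = 8.0e-05, and adjusted p = 0.17 with an estimated correlation), namely Pdgfrb at -0.92 ± 0.20 and Col1a1 at -0.83 ± 0.15.

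Among single genes lower in JEGS than in the leave-out mean were Slc2a10 at -2.25 ± 0.44, Pam16 at -2.22 ± 0.60, Copz2 at -2.01 ± 0.52 and Zc3h11a at -1.95 ± 0.39. Of 21 alternative settings, Pam16 failed to pass in 11, Copz2 in 8, Zc3h11a in 4 and Slc2a10 in 2, and Pdgfrb above in 4. Pakap, whose annotation overlaps Palm2 and Akap2 and whose counts are therefore uncertain, had no count in JEGS and was at least 13.3-fold lower. In all, 674 of 16603 genes passed, 533 higher and 141 lower, a count that 7 of 80 rearrangements of arm labels within days also reached, the real one included. It was 127 without the day 6 library of JEGS, 194 without its day 4 library, and 394, 398 and 436 without the day 4 library of the arms without Glis1, Jdp2 and Sall4.

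**Figure D2:**
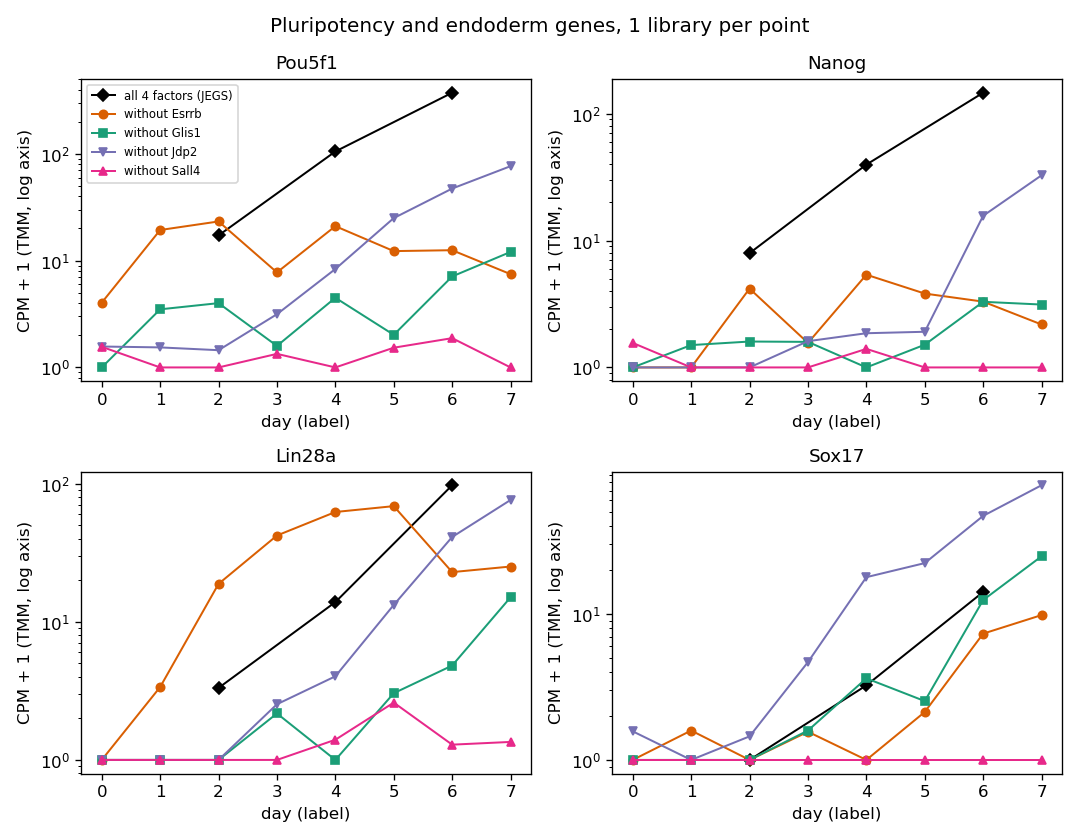
Levels of Pou5f1, Nanog, Lin28a and Sox17 by day on a log axis (CPM + 1, TMM scaling), with 1 point per library and 1 line per arm. Pou5f1 and Nanog are highest in JEGS on day 6, at 372 and 145 CPM, and rise late in the arm without Jdp2, to 75.6 and 31.7 CPM on day 7.

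Set against each leave-out arm alone, with 3 libraries against 3, JEGS was higher in pluripotency genes each time and differed further by arm. In the comparison with the arm without Glis1 they were higher in 21 of 27, or 23 adjusted over the list alone (camera adjusted p = 3.4e-11, and adjusted p = 0.35 with an estimated correlation). Against the arm without Sall4, pluripotency genes were higher in 24 of 27, or 25 adjusted over the list alone (camera adjusted p = 2.0e-11, and adjusted p = 0.35 with an estimated correlation). Among them were L1td1 at 8.69 ± 0.70, Pou5f1 at 8.57 ± 1.09 and Nanog at 8.51 ± 1.09. On days 2, 4 and 6 the arm without Sall4 had 0, 0 and 3 counts of Pou5f1 and 0, 1 and 0 of Nanog. The size of these 2 differences is therefore uncertain. Nanog stood at 6.45 without day 6 of that arm and at 10.42 without its day 4. Utf1 and Lefty2 were at least 127-fold and 60.9-fold higher there. All 28 cell cycle genes were higher too, with a median of 2.50 (camera adjusted p = 1.1e-22, and adjusted p = 0.35 with an estimated correlation). Members included Ccnb1 at 3.24 ± 0.37. In the comparison with the arm without Glis1, 26 of 28 were higher, or 27 adjusted over the list alone (camera adjusted p = 8.4e-15, and adjusted p = 0.35 with an estimated correlation). By edgeR none of the 28 passed in the comparisons with the arms without Esrrb and Jdp2, nor adjusted over the list alone, at medians of -0.14 and 0.22 (camera adjusted p = 0.36 and 0.018, and 0.91 and 0.77 with an estimated correlation). Relative to the arm without Glis1, interferon genes were lower in 19 of 22, or 20 adjusted over the list alone (camera adjusted p = 2.6e-12, and adjusted p = 0.35 with an estimated correlation). Ifi44 stood at -5.50 ± 0.62 and Ifit1 at -5.20 ± 0.76, and Usp18, with no count in JEGS, was at least 131-fold lower. Tlx3 was at least 34.4-fold higher and, among the salivary paralogs, Dcpp1 at least 55.0-fold higher. Against the arm without Esrrb, pluripotency genes were higher in 14 of 27, or 20 adjusted over the list alone (camera adjusted p = 8.4e-13, and adjusted p = 0.35 with an estimated correlation). Nr0b1 was higher there by 5.98 ± 0.77, or 9.34 without day 2 of that arm, and Spp1 by 3.09 ± 0.34. Abcb1a and Paqr5 were at least 13.7-fold and 13.9-fold higher, and Sp7 at -5.07 ± 0.51 and Col8a2 at -4.32 ± 0.44 were lower. Of 16 Wnt targets, none was higher in JEGS than in that arm and 3 were lower, or 6 adjusted over the list alone (camera adjusted p = 0.0084, and adjusted p = 0.35 with an estimated correlation).

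Against the arm without Jdp2, JEGS was higher in Nanog by 3.70 ± 0.67 and in Pou5f1 by 3.19 ± 0.65, and pluripotency genes were higher in 9 of 27, or 19 higher and 1 lower adjusted over the list alone (camera adjusted p = 8.0e-14, and adjusted p = 0.31 with an estimated correlation). Primitive endoderm genes were lower in JEGS in 6 of 17, or 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 4.2e-08, and adjusted p = 0.25 with an estimated correlation). These included Sox7 at -2.49 ± 0.51 and Col4a2 at -1.65 ± 0.20. The keratin Krt8 was lower at -2.87 ± 0.37 and the peptide hormone Pyy at -4.70 ± 0.46, while Gpx6 was higher by 4.78 ± 0.81 and the crystallin Crybb1 by 4.67 ± 0.56. Nanog and Pou5f1 each failed to pass in 5 of 21 alternative settings, Sox7 in 4, Gpx6 in 2 and Krt8 in 1, and Nanog stood at 5.86 without day 6 of that arm. The number of genes past the threshold was 3954 against the arm without Sall4, 3304 against that without Glis1, 1101 against that without Esrrb and 468 against that without Jdp2. Leaving out 1 library gave as few as 2160, 1815, 470 and 103, in that order.

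The day trend common to the 4 leave-out arms is the mean of their slopes and asks what changes with time in the medium. SRF and YAP targets and fibroblast genes fell and epithelial genes rose. All 17 SRF and YAP targets fell, also 17 adjusted over the list alone, with a median of -0.53 per day (camera adjusted p = 8.3e-10, and adjusted p = 0.35 with an estimated correlation). The smooth muscle genes Actg2 at -1.75 ± 0.12, Cnn1 at -1.03 ± 0.13, Acta2 at -1.01 ± 0.13 and Tagln at -0.86 ± 0.10 log2 units per day fell most, together with Fbln5 at -0.86 ± 0.08. Much of that fall came at once, since Acta2 stood at 4150 to 7963 CPM on day 0 and 287 to 388 CPM on day 1. Fibroblast genes fell in 19 of 29, or 20 adjusted over the list alone, with a median of -0.22 (camera adjusted p = 5.3e-12, and adjusted p = 0.33 with an estimated correlation). Among them were Lox at -0.73 ± 0.09 and Thy1 at -0.57 ± 0.06. Without day 0 these slopes were smaller, at -0.81 for Actg2, -0.24 for Cnn1, -0.46 for Acta2, -0.43 for Tagln, -0.44 for Fbln5, -0.25 for Lox and -0.31 for Thy1. Epithelial genes rose in 12 of 23, or 14 adjusted over the list alone (camera adjusted p = 6.7e-06, and adjusted p = 0.34 with an estimated correlation). Members included Grhl2 at 0.64 ± 0.11 and Epcam at 0.56 ± 0.06. Wnt targets rose in 13 of 16, or 14 adjusted over the list alone (camera adjusted p = 1.2e-06, and adjusted p = 0.31 with an estimated correlation). These included Notum at 0.49 ± 0.07. Pluripotency genes rose in 12 of 25 and fell in 1, or 14 and 1 adjusted over the list alone (camera adjusted p = 0.0027, and adjusted p = 0.31 with an estimated correlation). Cell cycle genes fell on average in 21 of 28, or 23 adjusted over the list alone, with a median of -0.15 (camera adjusted p = 2.4e-10, and adjusted p = 0.35 with an estimated correlation). That fall was not shared by all arms, as their mean log2(CPM + 1) went from 6.29 on day 0 to 3.77 on day 7 without Sall4 and from 6.74 to 5.79 on day 3 and back to 6.45 without Jdp2. The steepest rises were S100g at 1.08 ± 0.13, Cldn5 at 0.94 ± 0.11, Lin28a at 0.94 ± 0.15, AU015836 at 0.94 ± 0.15 and Elf3 at 0.79 ± 0.09, and 5658 genes passed, 2790 rising and 2868 falling.

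**Figure D3:**
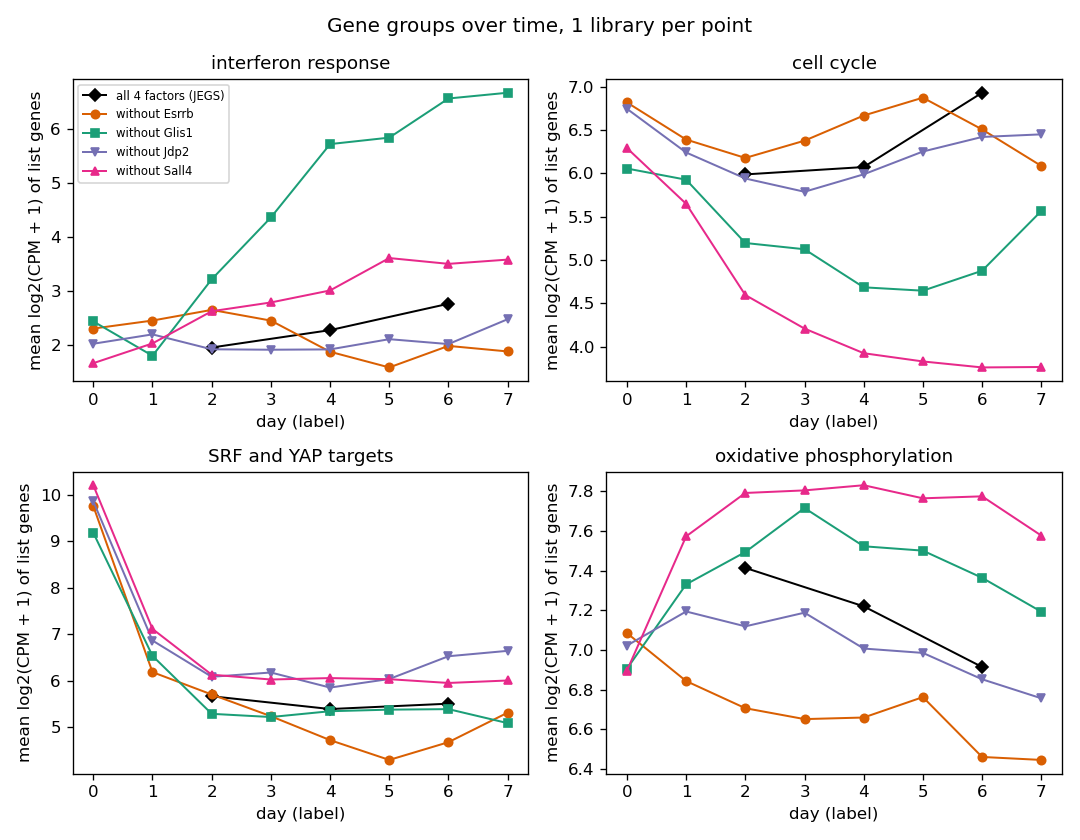
Mean log2(CPM + 1) of 4 gene groups by day, with 1 point per library and 1 line per arm. Interferon genes climb in the arm without Glis1, and cell cycle genes lie lowest in the arm without Sall4 from day 1 on, where 20 of 28 had a steeper fall than in the other leave-out arms.

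Arm-specific day trends ask whether an arm changes at another rate than the mean of the other 3 leave-out arms. In the arm without Glis1, 18 of 23 interferon genes rose faster, or 20 adjusted over the list alone, with a median difference of 0.82 log2 units per day (camera adjusted p = 6.9e-34, and adjusted p = 0.0043 with an estimated correlation). Ifit3 stood at 1.27 ± 0.14, Usp18 at 1.04 ± 0.18, Isg15 at 1.02 ± 0.14 and Oas1a at 1.02 ± 0.16, and Ifit1 itself went from 10.4 CPM on day 0 to 310 CPM on day 7. The chemokines Ccl7 and Ccl2 differed there by 0.95 ± 0.21 and 0.71 ± 0.15 and the hedgehog ligand Ihh by 2.13 ± 0.34, while Rspo1 stood at -1.64 ± 0.44 and Col8a2 at -1.58 ± 0.35. Of 46 alternative settings, Rspo1 failed to pass in 12, Ccl7 in 4 and Col8a2 in 3. Without day 0 they stood at -0.05, 0.45 and -0.23, without day 0 of that arm Rspo1 and Col8a2 stood at -0.17 and -0.33, and without day 0 of the arm without Esrrb Ccl7 stood at 0.54. In the arm without Esrrb, the slope difference of interferon genes went the other way in 12 of 23, or 17 adjusted over the list alone, with a median of -0.54 (camera adjusted p = 1.4e-13, and adjusted p = 0.26 with an estimated correlation). Part of that reference is the arm without Glis1, where their median log2 rise from days 0 to 2 to days 5 to 7 was 3.83. It was -0.44 in the arm without Esrrb itself. There Snai2 at 0.69 ± 0.10, Postn at 0.41 ± 0.05, Bmf at 0.90 ± 0.17 and Stab1 at 0.89 ± 0.14 rose relative to the other arms, and Pou5f1 at -0.68 ± 0.18 and Ccl7 at -1.46 ± 0.31 fell relative to them, of which Pou5f1 failed to pass in 8 alternative settings and Ccl7 in 3. Ccl7 stood at -0.54 without day 0, and at -0.23 and -2.24 without days 0 and 7 of that arm. The count for mt-Co2, at -2.87 ± 0.84, is uncertain and failed to pass in 13 of 46 alternative settings, as this gene is at 0 CPM in some libraries and at up to 269 CPM in others. It stood at -7.22 without day 0 and -0.66 without day 1, and at -7.21 and -0.70 without those days of that arm.

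In the arm without Jdp2, the slope differences of Nanog at 1.46 ± 0.29 (adjusted p = 0.032), Pou5f1 at 1.07 ± 0.23 (adjusted p = 0.048) and Gata4 at 0.87 ± 0.12 (adjusted p = 0.0014) passed. Pou5f1 failed to pass in 33 of 46 alternative settings, Nanog in 19 and Gata4 in 2. Primitive endoderm genes rose faster in 4 of 18, or 9 faster and 1 slower adjusted over the list alone (camera adjusted p = 2.3e-07, and adjusted p = 0.0024 with an estimated correlation). Hoxd13 at -0.46 ± 0.08 and Pcolce at -0.31 ± 0.05 fell relative to the other arms, but failed to pass in 4 and 2 settings. In the arm without Sall4, 20 of 28 cell cycle genes fell faster, or 27 adjusted over the list alone, with a median of -0.37 (camera adjusted p = 3.9e-30, and adjusted p = 0.27 with an estimated correlation). Bub1 stood at -0.52 ± 0.12 and Top2a at -0.49 ± 0.08, and the matrix genes Prelp at 1.08 ± 0.18 and Ccn5 at 1.05 ± 0.24 rose against Asb4 at -0.85 ± 0.13 and St3gal6 at -0.68 ± 0.16. Of the 46 settings, St3gal6 failed to pass in 7, Ccn5 in 6 and Bub1 in 5. Without day 0 of that arm St3gal6 stood at -0.28 and Ccn5 at 1.59, and without day 0 of the arm without Jdp2 Ccn5 stood at 0.70. Genes with a different slope numbered 1204 without Esrrb, 644 without Glis1, 334 without Sall4 and 23 without Jdp2. The last count moves with single days, up to 445 without day 0, and 5 of 80 rearrangements of days within arms reached it, the real one included, or 1 of 80 with the common trend kept.

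Against the mean slope of the leave-out arms over days 2, 4 and 6, JEGS differed in 44 genes, 19 with a higher and 25 with a lower slope, a count that 26 of 80 rearrangements of arm labels within days reached. The pluripotency genes Klf2 at 1.39 ± 0.28 and Tet2 at 0.57 ± 0.12 rose faster per day, as did the hypoxia-responsive Bnip3 at 1.54 ± 0.30, though all 3 failed to pass in 12 of 20 alternative settings. Cpt1b stood at -1.22 ± 0.21 and Acy3 at -0.79 ± 0.11, and these failed in 7 and 4. Klf2 stood at 2.72 and 4.46 without the day 4 and day 6 libraries of JEGS. Of 28 cell cycle genes, 1 passed, or 17 adjusted over the list alone (camera adjusted p = 1.4e-16, and adjusted p = 0.35 with an estimated correlation). These slopes rest on 3 libraries, and without the day 6 library of JEGS the count was 1.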

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

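For the interferon genes, the tests of immune cells, depth and culture state were chosen only after the result was seen, as were both tests of the gene counts of JEGS against single arms and the rearrangements of days that keep the common trend. Carry-over tests and the other rearrangements were chosen before their results were seen.

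Interferon-stimulated genes in the arm without Glis1 rose more over time than in any other leave-out arm. Their median log2 rise from days 0 to 2 to days 5 to 7 was 3.83 (95% bootstrap interval 3.48 to 4.63), and all 23 rose by more than 1. A rise carried by macrophages growing in number would raise macrophage genes to a like extent. These had a median rise of 0.071 with an upper bound of 0.377, and Lyz2 stayed between 3.06 and 7.64 CPM. The macrophage genes are low in this arm, at 23.5 to 47.2 CPM summed. Other immune cells, or cells that act without growing in number, were not tested. In the slope difference the macrophage list did move up (camera adjusted p = 0.025, and adjusted p = 0.31 with an estimated correlation), with 1 of 14 genes past the threshold, but its rise was far below that of the interferon genes. Greater depth of the later libraries is argued against as well, since 17 of the 18 genes still passed after thinning to 1200000 counts. Also open is a state of this culture unrelated to Glis1, because interferon genes also rose in the arm without Sall4, which received Glis1, with a median of 1.418 (interval 0.941 to 1.945), and each arm is 1 culture series. In that arm growing macrophages are not argued against, as macrophage genes had a median rise of 0.304 with an upper bound of 0.854, too near 1.418 to set them apart. Their slope difference was also upward there, in 1 of 14, or 6 adjusted over the list alone (camera adjusted p = 5.4e-05, and adjusted p = 0.064 with an estimated correlation). That loss of Glis1 may favour an interferon response is therefore a hypothesis.

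Esrrb stood at 57.9 CPM on day 2 of the arm without it, apart from the 7.06 to 19.0 CPM of its other 7 libraries. Carry-over of reads from another day 2 library would bring that library's own genes along. Genes abundant in the day 2 library of the arm without Jdp2 and near 0 in the other libraries without Esrrb, led by Ngp, S100a9 and S100a8, had 11 counts where carry-over predicts 11.5 above a background of 2.9. Those of the arm without Sall4 had 16 where it predicts 6.1 above a background of 4.5. For JEGS and the arm without Glis1 the sums were 13 and 17, but predictions of 3 and 4.6 counts, above 1.6 and 3.6, are too few to decide. Except for the arm without Jdp2, each sum was above prediction and background together, so the excess singles out no source. Carry-over of 0.683% to 1.75%, the range over the 4 sources, is a candidate explanation, and the source cannot be told apart. A prediction of 6.1 counts is itself small, genes picked for low counts elsewhere understate the background, and no biological explanation was tested.

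The 4 other values that stood apart from the rest of their arm were Glis1 at 4.44 CPM on day 0 without Glis1 (others at most 1.17), Jdp2 at 45.4 CPM on day 0 without Jdp2 (others at most 20.7), Sall4 at 11.2 CPM on day 0 without Sall4 (others at most 3.15) and Nanog at 31.7 CPM on day 7 without Jdp2 (others at most 14.7). They come from 32 groups of 8 libraries. Chance would pick out about 1 in 20 groups if the 8 were independent draws, but each group is a series over days. The Glis1, Jdp2 and Sall4 values are all from day 0. Nanog without Jdp2 was already rising, from 0.93 CPM on day 5 to 15.49 CPM on day 6 before TMM scaling.

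JEGS differed from the arm without Jdp2 in 468 genes, against 3304 and 3954 for the arms without Glis1 and Sall4. After thinning, the smaller of the latter counts was still 7.58 times the former, which argues against depth. A shared way of preparing libraries would bring the arm without Jdp2 nearest to JEGS in fragment length. Its median term lay 7.4 bases away, against 5.1 for the arm without Glis1 and 8.5 for that without Sall4. The nearest was the arm without Esrrb, at 4.7. Over all days the term spans 201.2 to 212.3 bases within the arm without Glis1. It spans less in others, with 205.7 to 209.5 without Jdp2 and 206.8 to 211.7 without Sall4, both apart from the 198.5 to 201.9 of JEGS. The order of the gaps is not the order of the gene counts, so the term does not decide and preparation stays open. The level of the shared factors differed as well. Before TMM scaling and over all days of an arm, Esrrb averaged 1877 CPM in JEGS and 1803 CPM without Jdp2. It averaged 6135 and 6145 CPM without Glis1 and Sall4. The kit of each library is not given in the sources used here. A batch, the level of the shared factors and the arm therefore cannot be told apart. A smaller part of Jdp2 in the set remains a hypothesis that could be tested with replicated cultures.

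Differences in day slope between arms were picked out because each is a test of the difference itself. Arrangements of days within arms, 80 with the real one, also remove the trend that arms share, so their low counts do not test equal slopes. When that trend was kept and days were rearranged in the arm-specific part alone, 1 of 80 gave as many in each arm, namely the real one. Without Esrrb 1204 genes differed (highest other 161), without Glis1 644 (21) and without Sall4 334 (3), so for these a chance order of the days can be excluded. A drift of a single culture for other reasons than the missing factor cannot, since each arm is 1 culture series. Without Jdp2 23 genes differed (highest other 4). In the first kind of arrangement 5 of 80 gave as many (highest other 274), against 1 of 80 in the other 3 arms. That kind does not test equal slopes, but the count also fell to 0 by edgeR when day 6 was left out. With the common trend kept, only the real order of days gave as many there, as in the other arms. Because the count depends on single days, no conclusion on chance is drawn for that arm. For JEGS 44 genes differed, and 26 of 80 arrangements of arm labels within days gave as many (highest other 1671). Such arrangements can put libraries of other arms, which may differ in slope, under the JEGS label. The share therefore does not decide the question, and chance is neither excluded nor shown for JEGS. The source of the larger counts was not tested.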

How the results depend on the processing

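Thinning to one depth was chosen only after the data were seen. The leave-out contrasts and the common trend stayed within 1.5 times of their counts in all alternatives and when each library or day was left out (6772 to 8297 genes without Esrrb, 5537 to 7205 without Glis1, 2858 to 5106 without Jdp2, 6244 to 8096 without Sall4, 4575 to 6794 for the trend). Their balance of higher and lower genes was less stable. Limma-trend on TPM gave 57.4%, 42.6% and 41% higher without Esrrb, Glis1 and Sall4 (by edgeR 48.9%, 55.1% and 53.4%), and 59.9% and 60.7% for JEGS against the arms without Glis1 and Sall4 (by edgeR 49.5% and 49.8%). Of 101 counts under other settings, 83 stayed within 1.5 times, 11 were higher and 7 lower. The cause was not tested except where named. Without a filter, which adds genes to the test, JEGS differed from the leave-out mean in 1565 genes, from the arms without Esrrb and Jdp2 in 1773 and 1122, and in slope in 307. Limma-trend on TPM gave 110, 653 and 209 for those 3 comparisons and 73 and 169 slope differences without Jdp2 and Sall4. For JEGS slopes it gave 0, with 1962 genes at an unadjusted p under 0.05, where edgeR gave 44. The DESeq2 Wald test gave 987, 90, 635 and 78 slope differences without Glis1, Jdp2, Sall4 and for JEGS. Thinning gave 8, 200 and 68 without Jdp2, Sall4 and for JEGS, and log2(day + 1) gave 552 without Sall4. With an estimated inter-gene correlation, 2 of 444 list tests passed in place of 152.

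Single libraries moved the JEGS counts. Against the leave-out mean they ran from 127 (without JEGS day 6) to 923, with 194 without JEGS day 4. With the arm without Esrrb they ran from 470 (without JEGS day 4) to 1119, with 607 without JEGS day 2 and 615 without day 4 of that arm. With the arm without Glis1 they ran from 1815 (without its day 4) to 3786, with 1941 without JEGS day 6. With that without Jdp2 they ran from 103 (without its day 4) to 619, with 138, 153, 241 and 260 without JEGS day 4, its own day 2, JEGS day 6 and JEGS day 2. With that without Sall4 they ran from 2160 (without JEGS day 6) to 4534, with 2349 and 2587 without days 6 and 4 of that arm. Slope counts ran from 363 (without day 6) to 1536 without Esrrb, with 611 without day 6 of that arm. They ran from 227 (without day 6) to 926 without Glis1, with 416 without day 5 and 370 and 368 without days 0 and 6 of that arm. Without Sall4 they ran from 93 (without day 6) to 619 (without day 0 of the arm without Jdp2) and moved over 1.5 times in 9 of 40 cases. Without Jdp2 they ran from 0 (without day 6, by edgeR, with 1155 genes at an unadjusted p under 0.05) to 445 (without day 0) and moved over 1.5 times in 27 of 40 cases. For JEGS they ran from 1 (without JEGS day 6) to 303 and moved over 1.5 times in 11 of 15 cases.

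For the 172 fitted values of single genes in the report, no direction changed in 7205 refits. In 240 of these, for 44 of the values, the gene no longer passed. Leaving out a library or day moved 20 of the values over 1.5 times, in 31 of 5905 cases, and these are given in the report. No list past the camera threshold changed the sign of its median in 760 tests under other scalings. Limma-trend moved the median of all genes from -0.01 to 0.10 for JEGS against the arm without Glis1, and removing the filter moved it from -0.01 to -0.16 without Esrrb and from 0.02 to -0.12 for JEGS against the mean. Depth limits genes near 1 CPM, where 1 count is 0.277 to 0.79 CPM. Arms were compared within days, with day as a factor, and without the day term the count without Jdp2 was 2858. Beyond the shared day, no paired analysis was possible because the labels give no replicate numbers that pair the libraries.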

Other observations

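Only the comparison of library pairs was a test chosen after the data were seen. Complement and lysozyme genes of macrophages were higher without Sall4, in 5 of 14 list genes, also 5 adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.35 with an estimated correlation), with C1qc at 3.10 ± 0.43, C1qa at 2.85 ± 0.45, C1qb at 2.65 ± 0.45 and Lyz2 at 2.27 ± 0.37. Without Glis1, 1 of 14 was higher and 1 lower, the former being Csf1r at 2.26 ± 0.38. Members of the NuRD complex were higher in 7 of 13 and lower in 2 without Esrrb, and lower in 8 and higher in 2 both without Glis1 and without Sall4, with the same counts adjusted over the list alone (camera adjusted p = 0.048, 0.044 and 0.036, and 0.49, 0.49 and 0.47 with an estimated correlation). Cholesterol synthesis genes were lower in 10 of 19 without Esrrb, also 10 adjusted over the list alone (camera adjusted p = 0.027, and adjusted p = 0.72 with an estimated correlation). The 13 mitochondrial transcripts were lower in 10 without Esrrb and in 8 without Jdp2, and higher in 8 without Glis1 and in 10 without Sall4, with the same counts adjusted over the list alone (camera adjusted p = 0.00019, 3.4e-06, 6.6e-05 and 0.0039, all lost with an estimated correlation at adjusted p = 0.35, 0.35, 0.35 and 0.49). They took 1.61% to 6.07% of counts in the leave-out libraries and 4.17% to 5.13% in JEGS.

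Markers of other lineages divided within their lists. Cartilage and bone genes were higher in 6 of 12 and lower in 2 without Glis1, or 6 and 3 adjusted over the list alone, with Matn4 at 5.05 ± 0.25, and lower in 6 of 12 and higher in 1 without Sall4, with Sp7 at -4.55 ± 0.61 (camera adjusted p = 0.095 and 0.11). Neural genes without Esrrb were lower in 2 of 11, with Nefm at -3.24 ± 0.41 (camera adjusted p = 0.5). Genes of the unfolded protein and amino acid stress response were higher in 7 of 18 without Jdp2, and lower in 7 and higher in 2 without Sall4 (camera adjusted p = 0.084 and 0.16). AP-1 subunits went 6 higher and 4 lower of 12 without Sall4 (camera adjusted p = 0.74). Trophoblast genes, at 4 higher and 4 lower of 9, muscle genes, at 1 higher and 3 lower of 11, keratinocyte genes, at 4 higher and 3 lower of 8, adipocyte genes, at 1 higher and 2 lower of 6, and germ line genes, at 1 higher of 5, did not pass as sets without Esrrb (camera adjusted p = 0.84, 0.36, 0.81, 0.99 and 0.36). Of 5 sex-linked genes, 2 were lower without Sall4 (camera adjusted p = 0.19). For the other comparisons in this paragraph the counts adjusted over the list alone were the same.

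Other groupings of the libraries were compared with the real arms. Rearranging arm labels within days in 80 ways, the real one included, gave at most 163 genes for the contrast without Esrrb (real 7767), 4754 without Glis1 (6586), 2879 without Jdp2 (4269) and 5675 without Sall4 (7586), 1 of 80 each. A chance sorting of libraries into arms can therefore be excluded for all 4. A chance difference between single cultures cannot, since each arm is read as 1 culture series whose libraries may not be independent. Nor can a batch difference between arms, since kits and runs are not assigned to libraries. Why some arrangements gave high counts was not tested. Days rearranged within arms gave at most 848 genes for the common trend (real 5658), so a chance order of these libraries in time can be excluded. For JEGS against the leave-out mean, 7 of 80 arrangements gave as many as the real 674 genes (highest other 4287). Such arrangements can put libraries of a leave-out arm that differs from the rest together under the JEGS label. The share therefore does not decide the question, and chance is neither excluded nor shown for that count. The source of the larger counts was not tested. For JEGS against single arms only 4 splits exist, too few for a share under 0.05. The highest count of the others was 1 against the real 1101 and 3304 for the arms without Esrrb and Glis1, and 0 by edgeR against the real 468 and 3954 for those without Jdp2 and Sall4. All 595 pairs of libraries were compared for repeated data, and the closest pair, days 3 and 4 without Sall4, had a chi-square per gene of 2.57, above the value of 1 that repeated draws of the same RNA would give.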
